A study of Mus musculus with 2 samples.

How the data were processed

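Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for H3K27me3, the trimethylation of lysine 27 of histone H3 that Polycomb repressive complex 2 deposits, was done on primary regulatory T cells of an adult male mouse, per the labels. The labels give 2 libraries, technical replicates 1 and 2 of a single biological replicate, both from the same biosample and the same donor animal, aged 4 months. The number of biological replicates is therefore 1, the spread between the libraries is technical, and no comparison between conditions can be made. No control immunoprecipitation, input library, other antibody or other cell type was used here.

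The authors deposited 1 table per library that holds a count for each of 33643 numbered features. The deposited file descriptions give the assembly as mm10, call the table an enrichment quantification, and state that it was derived from the library's alignments and from 1 further file. That further file was not used here, and the deposited tables hold only a feature number and a count, so no feature could be tied to a gene, a chromosome position or a width. The aligner, the counting tool, any removal of duplicate reads and the definition of the features are not given in the sources used here. The values were whole numbers with unequal totals, and were read as raw counts despite the name of the table. Whether an input was used to make them is not given in the sources used here, and no division by an input or by feature width was made in computing the results. A wide feature can therefore hold more counts than a narrow one at the same density of the mark.

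The total over features was 303066 counts in library 1 and 304653 in library 2. These are the counts inside the features, not the sequencing depth of the libraries, which is not given in the sources used here. The median feature held 7 counts in each library, so counting error was large at a typical single feature. It made up most of the difference between the libraries there. Intervals of ratios of counts cover counting error only and take reads as independent, although reads without molecular identifiers are not independent molecules. Intervals of the block quotients and of shares of features cover the spread between features. They take features as independent, although features with adjacent numbers had related counts, so they can be too narrow. No interval covers biological variation.

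The comparisons were fixed before the data were examined, except where stated. Agreement of the libraries was measured by Spearman's rho and by Pearson's r of log2(count + 1) across features, which are not independent replicates, so no p-value is attached to a correlation. The pseudocount of 1 was the smallest value above 0. A chi-square test compared the 2 libraries' counts over features. High-count features were those at or above the lowest count that at most 5% of features reached, and differences were counted where the log2 ratio of library 2 to library 1, centred on its median, exceeded 1 in size. The value at no difference beyond counting was not part of this plan and was added later. For it, the summed count of each feature was divided between the libraries binomially 1000 times. Pearson's r of untransformed counts, with and without the Poisson part of the variance, was also added later. So was the treatment of the highest features as a separate group. Alternatives fixed in advance were another top share, a filter on features below the median of both libraries, each library alone, and scaling by total count, by edgeR's TMM or by DESeq2 size factors. Neither tool was used for a test, since each would need replicates of 2 groups.

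Also added after the data were examined was a two-sided exact binomial test per feature with Benjamini-Hochberg adjustment at 0.05. The scan along the feature numbers was added then too. So was the ratio of the libraries in doubling classes of summed count, with exact 95% binomial (Clopper-Pearson) intervals. Quotients of 2 such ratios had 95% intervals from the counts on the log scale. Both of these tests on reads compare the 2 libraries, not conditions. In the scan, windows of 100 consecutive features were kept where the share of features with 4 counts or fewer was above the highest share in 1000 shuffles of the order. Overlapping windows were merged into blocks whose ends were placed by binomial likelihood. Each block was then measured in the library not used to find it, as a mean trimmed by 10% at each end, against up to 300 features on each side, with a 95% interval from 10000 bootstrap resamples of the features.

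The rule for named features was to give the 10 with the highest mean rank in the top 5% of both libraries and the 5 with the largest difference in each direction. Because a feature number identifies no gene, numbers are printed for the 2 with the highest mean rank and 2 of those higher in library 2, and the others are given as values or ranges of values. Of the planned results, 2 were not computed: the levels over the gene lists that had been fixed, and the distribution over chromosomes, both of which need feature positions.

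The test per feature was tested on simulated data with the real features' means. With 33643 unchanged features it called 0. Among 200 features changed 2-fold it recovered 0.5% when they were drawn from all features and 49% when drawn from features with 80 or more summed counts. For 4-fold changes it recovered 18% and 97%, respectively. The simulated counts held Poisson noise only, so these rates do not cover variation beyond counting. The real features with 80 to 159 and 160 to 319 summed counts varied more than that (chi-square per degree of freedom 1.11 and 1.39 within class). The scan found both of 2 planted blocks of 150 and 500 features at reduced counts. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.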

Results

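H3K27me3, a histone mark associated with genes silenced by Polycomb, was profiled in regulatory T cells, the CD4 T cells that restrain immune responses and are defined by the transcription factor Foxp3. The cells came from an adult male mouse carrying a tamoxifen-inducible Cre recombinase at Foxp3 and a yellow fluorescent protein reporter at Rosa26. The labels trace the primary cells to a bone marrow haematopoietic origin and give neither an activation state nor a treatment. The data comprised 2 technical libraries of 1 biological replicate, called library 1 and library 2 here, each with a whole-number value, read as a raw count, for the same 33643 numbered features. The features carried no gene name or coordinate, so the regions below are described by their counts and their numbers.

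H3K27me3 counts were unevenly spread over the features. Most features held few counts: the median was 7 in both libraries, and the quartiles were 4 and 11 in library 1 and 4 and 10 in library 2. The 99th percentile was 47 counts in library 1 and 53 in library 2, and the highest feature held 708 and 557 counts. Features in the top 5% held at least 24 counts in library 1 and at least 25 in library 2. These 1655 and 1668 features took 21.8% of all counts in library 1 and 23.7% in library 2. The variance across features was 13.0 times the mean in library 1 and 13.2 times in library 2, where counts with a common rate would give 1. Without the 9 highest features these values were 8.46 and 10.3. A count of 0 was found at 345 features in library 1 and at 381 in library 2, and at 32 features in both. At the mean rates a Poisson distribution would give 4.12 and 3.93 features with 0 in the respective library. For a feature chosen in advance, a count of 0 allows a mean of up to 3 counts, so a 0 does not show that the mark was absent. This limit does not hold for features picked because they held 0. All but the 32 features with 0 in both libraries held counts in the other library, such as feature 1054 with 0 and 10. Feature widths were not used here and can contribute to the spread of the counts.

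The first comparison asked how well the 2 technical libraries agreed. Across features the counts had a Spearman's rho of 0.65 and a Pearson's r of 0.70 on the log2(count + 1) scale. Binomial division of the summed counts gave a mean rho of 0.66, with 95% of divisions between 0.65 and 0.66, and a mean r of 0.70. The rank agreement was thus within the range that counting error alone allowed at this depth. Pearson's r of the untransformed counts was 0.910, below the range of 0.921 to 0.925 in the divisions. With the Poisson part of the variance removed it was 0.985, and 0.996 without the 9 highest features. The 2 libraries did differ by more than the sampling noise of independent reads, and the reads here may not be independent. The chi-square statistic was 34541 on 33610 degrees of freedom (p = 1.9e-04, upper tail), or 1.03 per degree of freedom. When each feature was compared with the ratio of its own count class the chi-square statistic fell to 1.01 per degree of freedom (p = 0.041). Within classes it was 1.11 for the 523 features with 80 to 159 summed counts and 1.39 for the 56 with 160 to 319. In the other classes it lay between 0.73 and 1.01. Binomial intervals of ratios in those 2 classes can therefore be too narrow. The 2 libraries thus did not hold identical counts, and they were treated as technical replicates of 1 biological replicate.

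**Figure D1:**
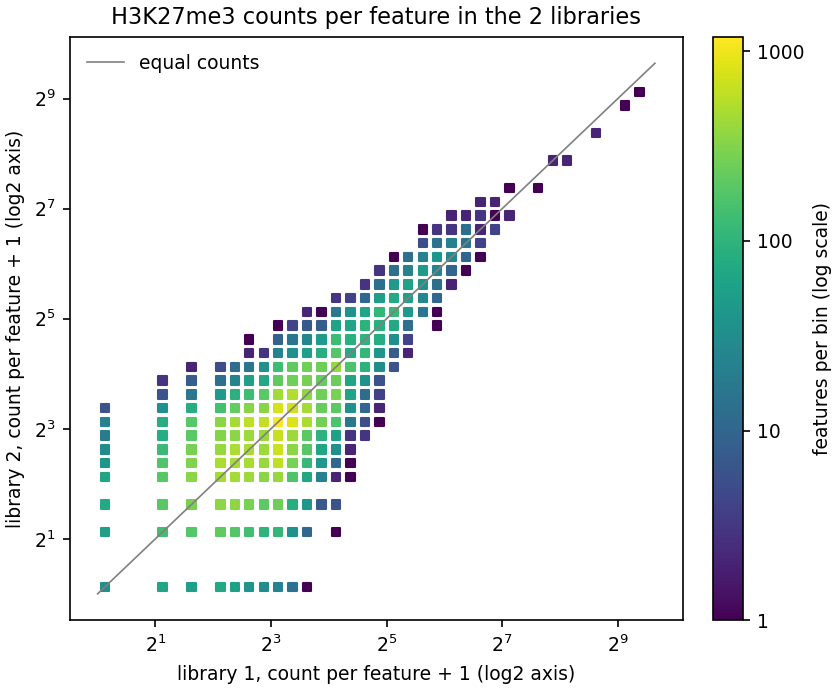
Counts per feature plus 1 in library 1 (horizontal, log2 axis) against library 2 (vertical, log2 axis), binned in log2 steps of 0.25 and coloured by the number of features per bin; the line marks equal counts. Features with few counts scatter widely around the line, features with many counts lie close to it, and most of the 9 features with the highest counts lie in bins below it.

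The high-count features were largely shared between the libraries. Of the features in the top 5%, 1314 were in the top 5% of both libraries, which was 79.4% of the shorter set. Independent rankings would share 82.1 features, and binomial division of the summed counts gave 1281 on average (95% of divisions from 1259 to 1318). In the top 1%, 262 features were shared, or 80.4% of the shorter set, and in the top 10% 2325 were shared, or 76.9%. The feature with the highest mean rank was number 6635, with 708 counts in library 1 and 557 in library 2. Feature 18076 was next, with 580 and 443 counts. The 7 features that followed held between 207 and 404 counts in library 1 and between 173 and 310 in library 2. The 10th had 129 counts in library 1 and 168 in library 2. The 9 highest features stood alone in the numbering: the median summed count of their direct neighbours was 15.5 and the highest was 64.

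The second comparison asked which features differed between the libraries. The totals differed by 0.52%. A log2 ratio above 1 in size was found at 4655 features, 2134 of them higher and 2521 lower in library 2. A further 1028 and 1190 features lay at exactly 2-fold higher and lower and were not counted. No direction can be read from this split, since scaling by TMM moved the first of these tied sets over the limit (3162 higher and 2521 lower) and scaling by total count the second (2134 and 3711). With median centring, binomial division of the summed counts gave 4582 such features on average (95% of divisions from 4458 to 4705), so their number did not exceed counting error. All but 18 of them had fewer than 40 summed counts. Those 18, of 2241 features with 40 or more summed counts, comprised 13 higher and 5 lower in library 2. The largest centred log2 ratios belonged to features with 0 counts in a library. Features 1054 and 32200 had 0 counts in library 1 and 10 in library 2, and the other 3 features of the 5 most extreme in this direction had 0 and 9. In the other direction the most extreme feature had 12 and 0 counts and the following 4 had 10 and 0. None of these had an adjusted p below 1 in the exact binomial test.

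No single feature passed the two-sided exact binomial test over all 33643 features after Benjamini-Hochberg adjustment. The lowest adjusted p was 0.25, and 1224 features (3.64%) had an unadjusted p under 0.05 in this exact binomial test. In 1 binomial division of the same counts 1141 features did. The spread over divisions was not computed for this number, so whether 1224 exceeds counting error was not tested. The 2 lowest p-values belonged to the 2 highest features. Library 2 held 0.787 times the counts of library 1 at feature 6635 (95% interval 0.703 to 0.880, exact binomial p = 1.5e-05) and 0.764 times at feature 18076 (0.673 to 0.866, exact binomial p = 1.3e-05). Both passed when only the 8999 features with 20 or more summed counts were tested, with an adjusted exact binomial p of 0.0046 each. That test took its expected ratio from the totals of those 8999 features, where library 2 held relatively more counts than over all features. The pass therefore came with a changed expected ratio as well as with fewer tests.

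Differences between the libraries were resolved when features were grouped by their summed count. Features with moderately high counts were higher in library 2, and both the features with low counts and the 9 highest features were lower in it. The ratio of library 2 to library 1 was 0.968 (95% exact interval 0.954 to 0.984) for the 9695 features with 1 to 9 summed counts and 0.964 (0.955 to 0.972) for the 14917 with 10 to 19. It was 0.999 (0.990 to 1.01) for the 6758 features with 20 to 39 and 1.07 (1.06 to 1.09) for the 1653 with 40 to 79. The highest ratio was 1.13 (1.11 to 1.15), for the 523 features with 80 to 159 summed counts, of which 377 were higher and 127 lower in library 2. The 56 features with 160 to 319 had a ratio of 1.09 (1.05 to 1.14). At the 9 features with 320 or more the ratio was 0.814 (0.773 to 0.857), and all 9 were lower in library 2, with single ratios from 0.762 to 0.914. The top 5% of features by summed count, 1632 in number, held 21.3% of the counts of library 1 and 23.2% of those of library 2. Their ratio was 1.11 times that of the other features (95% interval 1.10 to 1.13).

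**Figure D2:**
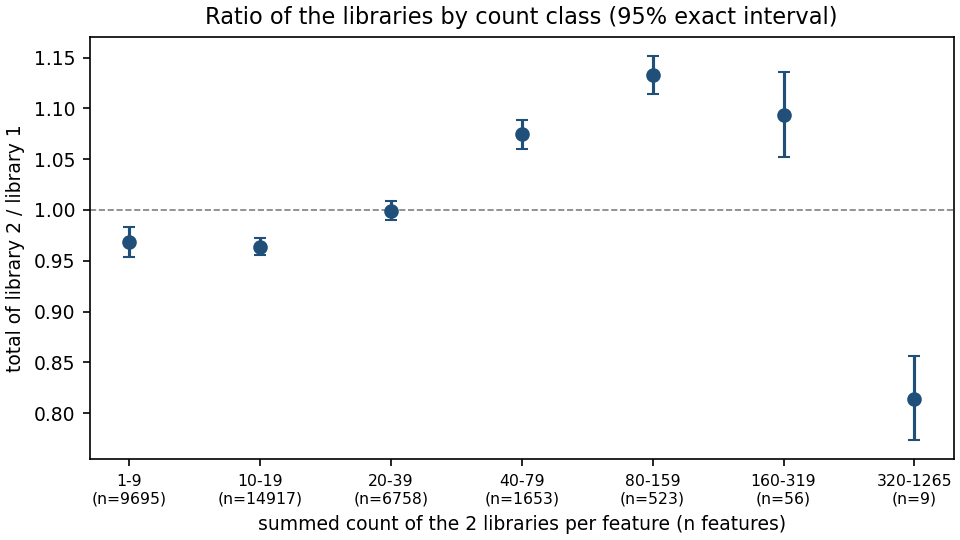
Total count of library 2 divided by that of library 1 (vertical axis, which does not start at 0) for features grouped by the summed count of both libraries (horizontal axis, with the number of features); points are ratios and bars are 95% exact binomial intervals. The ratio lies between 0.964 and 0.968 in the 2 lowest classes, reaches 1.13 at 80 to 159 summed counts and is 0.814 at the 9 highest features.

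Counts were also not spread evenly along the feature numbers. Blocks of consecutive features held fewer counts than their neighbours in both libraries. The share of features with 4 counts or fewer was 27.8% in library 1 and 29.6% in library 2 over all features. It reached 75% in a window of 100 features in library 1 and 81% in library 2. The highest share in any window of 1000 shuffled orders was 52% and 54%. The scan of library 2 found 3 blocks, comprising features 20111 to 20633, 25825 to 25938 and 33500 to 33642. The scan of library 1 found the first and second of these, at features 20109 to 20633 and 25824 to 25939, and not the third.

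Each block was measured in the library that had not been used to find it. In library 1 the first block had a trimmed mean of 3.32 counts against 7.63 in the flanking features, a quotient of 0.435 (95% interval 0.395 to 0.478). The second block had 3.45 counts against 7.36, a quotient of 0.468 (0.390 to 0.558). The third had 5.00 counts against 7.93, a quotient of 0.631 (0.527 to 0.749). In library 2 the first and second blocks, as found in library 1, had quotients of 0.414 (0.377 to 0.453) and 0.459 (0.384 to 0.538). In the first block of library 2, 5 of 523 features (0.956%) were in the top 5% of library 1, against 5.35% of the flanking features. The second block had 4 such features (3.51%, against 6.35% of its flanks) and the third had 2 (1.40%, against 5.65%).

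**Figure D3:**
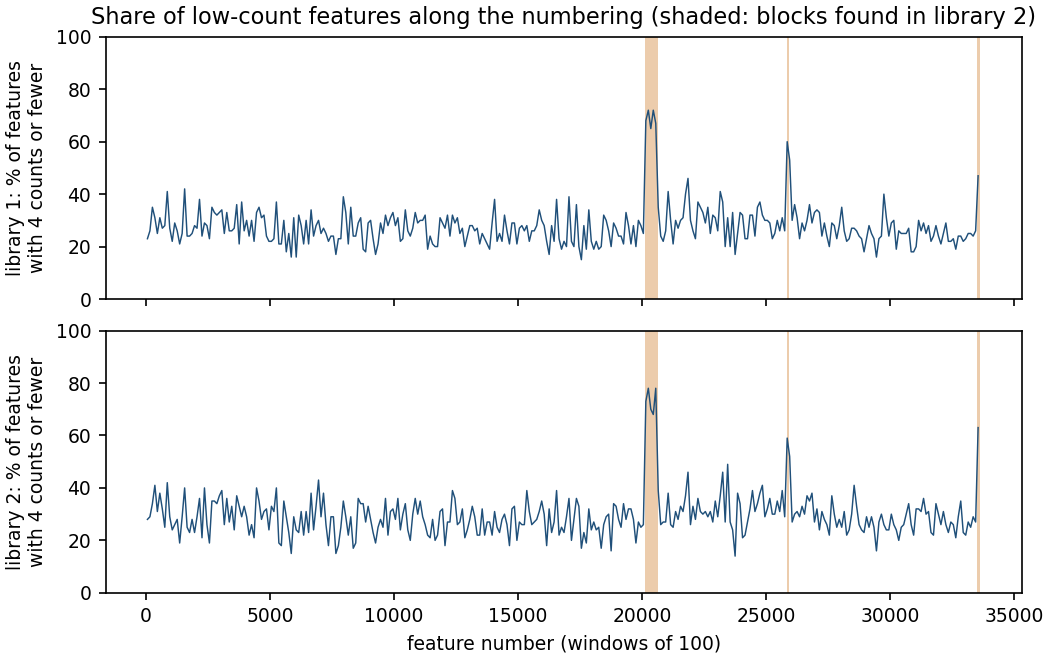
Percentage of features with 4 counts or fewer (vertical axes, 0 to 100) in consecutive windows of 100 features along the feature numbers (horizontal axis) in library 1 (upper panel) and library 2 (lower panel); shading marks the 3 blocks found in library 2. Both libraries rise at the shaded blocks above a level of 27.8% and 29.6% over all features. The rise at the third block is small in library 1. Its window from feature 33501 reached 47%, under the 52% of shuffled orders, and the unshaded window from feature 21801 reached 46%.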

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

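The alternatives that drop the 9 highest features or the low-count blocks, use a pseudocount of 0.5 or test only features with 20 or more summed counts were chosen after the data were examined. Of 37 alternatives, 27 kept a value within its counting spread or a count within 1.5 times and 10 moved it. The 27 include settings equal to the main one: the pseudocount of 1, and DESeq2 size factors, which were 1 in both libraries. They also include each library's top 5% alone, whose size the threshold sets. The tally is therefore no measure of robustness. Without features below the median of both libraries, Spearman's rho fell from 0.65 to 0.49, and Pearson's r of log2 counts from 0.70 to 0.60. Dropping the features low in both libraries can by itself lower a correlation, and how much of the fall this made was not tested. Features over 2-fold apart fell from 4655 to 2986, with 21990 features used instead of 33643. The rank correlation was 0.649 without the low-count blocks, and r was 0.673 with a pseudocount of 0.5. The planned pseudocount of 1 equalled the one used. Features shared at the top numbered 262 for the top 1% and 2325 for the top 10% by construction, against 1314 for the top 5%. Either library alone gave 1655 or 1668. Total counts and TMM shifted every log2 ratio by less than 0.02 and moved features tied at exactly 2-fold over the limit, as did the pseudocount of 0.5. Total counts gave 5845 features over 2-fold apart (36.5% higher in library 2), TMM 5683 (55.6%) and the pseudocount 6873 (46.0%), against 45.8% with median centring or DESeq2 size factors. The exact binomial test called 0 features over all features and 2 among those with 20 or more summed counts, where the expected ratio was also taken from the tested features. The ratio of the top 5% to the other features, 1.11, stayed between 1.10 and 1.13 with other top shares, without the 9 highest features and without the blocks. Depth limited single features: the median summed count was 13. No paired analysis was possible because there is a single group. Alternatives that need gene names, widths or positions were not run.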

Other observations

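Tests in this part were chosen after the result was seen. Only for the comparison within runs of feature numbers was the prediction written before it was made. That comparison still reused the counts that showed the rise of the ratio with the count, in runs cut at blocks found in these data. The 3 blocks of low counts were used to divide the numbering into 3 runs, each taken to end with a block: features 1 to 20633, 20634 to 25938 and 25939 to 33643. High-count features were unequally spread over these runs. The top 5% by summed count took 713 of 20633 features in the first run (3.46%, 95% Wilson interval 3.21 to 3.71), 371 of 5305 in the second (6.99%, 6.34 to 7.71) and 548 of 7705 in the third (7.11%, 6.56 to 7.71). The median summed count outside the blocks was 13, 13 and 14 in the respective run, so the first run differed from the others in its upper tail more than in its median. What distinguishes the features of the runs is not given in the sources used here. Features with adjacent numbers had related counts: the log2 count of a feature in library 1 had an r of 0.144 with that of the next feature in library 2, against a range from -0.019 to 0.018 in 1000 shuffles. This r was 0.092 at a distance of 2 numbers, 0.057 at 5 and 0.026 at 10, across features, which are not independent replicates. The Wilson intervals of the runs and the bootstrap intervals of the blocks leave this relation out and can be too narrow.

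The low-count blocks had fewer counts than their flanks in both libraries. A fault of 1 library is argued against, because the highest upper limit of any block's quotient to its flanks in the other library was 0.749, under the bound of 0.8. One hypothesis is that the features were numbered by chromosome in 3 successive lists and that each block is a single-copy chromosome in male cells, such as the X, which would give a quotient near 0.5: the pooled quotient was 0.473 (95% interval 0.439 to 0.509) in library 1, over the 3 blocks found in library 2, and 0.430 (0.398 to 0.465) in library 2, over only the first and second, which were found in library 1. The intervals of the first block lay under 0.5 in both libraries and that of the third in library 1, 0.527 to 0.749, lay above it. Narrower or less mappable features, or less of the mark there, cannot be told apart from this, because the low level was known before the hypothesis was set and the files hold 0 columns that give a width, a mappability or an input.

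The ratio of library 2 to library 1 rose with the count up to 80 to 159 summed counts. A difference in depth is argued against, since 1 factor would scale every class alike, whereas the ratio in that class was 1.18 times (95% interval 1.15 to 1.20) that in the class of 10 to 19. The rise was present in each run: the ratio in the top 5% of features was 1.10 (1.08 to 1.12), 1.12 (1.09 to 1.15) and 1.13 (1.11 to 1.16) times that in the other features. A higher signal over background in library 2, such as a more efficient immunoprecipitation, stays open as a cause, since the runs hold the same counts that showed the rise and no input was used here. No biological explanation was tested, because both libraries come from the same biosample.

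The 9 highest features went against that rise and were lower in library 2. If these 9 mainly hold signal, higher signal over background in library 2 is argued against as the cause, since their ratio was 0.814 with an upper limit of 0.857, under the lower limit of 1.11 of the class of 80 to 159. If they mainly hold background, a lower background in library 2 stays open. Their ratio was 0.844 times (95% interval 0.801 to 0.888) that of the features with 1 to 19 summed counts, which can mix signal and background. If those low-count features held background only, a value of 1 would follow, so this explanation needs them to hold signal too. The check could not decide, since any ratio at or under theirs was counted as a fit after the 9 were seen to be lower. The single ratios of the 9 features did not differ detectably from one another (chi-square p = 0.66 on 8 degrees of freedom). Reads shared between repeat copies, or a different share of duplicate reads, stay open and were not tested, since positions and duplicate rates were not used here.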
